A study of Drosophila melanogaster with 31 samples.

How the data were processed

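The samples were ovarian somatic cells grown at 26 degrees C, with RNA sequencing (7 samples), H3K9me3 chromatin immunoprecipitation (4) with inputs (2), CLIP of myc-Nxf2 with and without UV (6), CLIP of myc-Nxf2 after knockdown (8), CLIP of Piwi (3) and Piwi-bound small RNA (1). Per the labels, the CLIP knockdown cells were also depleted of endogenous Nxf2, and the RNA libraries were poly(A)+. The column header of the EGFP-KD IP does not name Nxf2, unlike the other count columns of that experiment. Depletion of endogenous Nxf2 in that IP therefore rests on the labels alone.

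The deposited tables hold read counts per transposable element consensus entry, in 1 column per condition, and the labels do not state whether these pool the replicates. For RNA sequencing the authors also gave RPKM, counts scaled by element length in kb and by a library total. The Nxf2-KD column has no unit in its header, but its values follow from the counts as in the other 3. For CLIP and small RNA the authors gave RPM, counts scaled by a library total. The deposited H3K9me3 peak lists of Nxf2-KD and Panx-KD cells give a score per peak on the dm3 genome build, merged over replicates per the file names. Per the labels, the tools were Bowtie2 2.2.9, Bowtie 1.0.1, TopHat2 2.0.14 and DESeq2 for RNA, cutadapt, STAR, SAMtools and Bowtie for CLIP, cutadapt and Bowtie for small RNA, and cutadapt, Bowtie 1.0 and MACS 1.4.2 for chromatin, with no role or order stated.

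Library totals were recovered as counts over normalised values. For each comparison the ratio of reads per library total was computed with an exact 95% conditional binomial (Clopper-Pearson) interval, and the Piwi-KD or UV effect on IP over SMInput as a ratio of ratios with an exact conditional odds ratio interval. Elements with a mean of at least 1 RPKM or RPM over the libraries of a table were tested. An element was called higher or lower at a ratio of at least 2 or its inverse with an interval excluding 1. Against 0 reads the ratio was computed with a floor of 3 counts in place of the 0, which is not a limit of the interval. No ratio was given where the other side was at or under this floor as well. The linear models planned with limma or edgeR need replicate columns and could not be fitted, so these counting intervals replaced them after the tables were seen, and no p-value compares conditions. Data were simulated 20 times per comparison, with rises only. Rises of 2.5-fold were recovered in 98% of elements for Nxf2-KD RNA, 64% for the EGFP-KD CLIP and 45.5% for the Piwi-KD effect. Falls were not simulated, so these shares do not tell how often falls in the Piwi-KD effect would be found. The simulated false calls were 0.143%, 0.938% and 1.88%. These draws held Poisson counting variation only. Both rates therefore leave out any spread between samples and are not error rates of the calls below.

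The comparisons, lists, named elements and most alternatives were chosen before the data were examined. Exceptions are the comparisons of Piwi-KD with Nxf2-KD RNA, of no-UV IP with its SMInput, between the SMInputs, of Piwi-KD IP with its SMInput and of the UV effect over SMInput. The 7 lists were somatic LTR, other gypsy-superfamily LTR, copia and Bel/Pao LTR, telomeric non-LTR, other non-LTR, DNA transposons and germline-dominant elements. Names were matched without case, punctuation, a DM prefix or the word element, a rule completed after the names were seen. Of 21 fixed elements 20 were matched, and springer was not. Of the 5 telomeric names 2 were matched, and TART and TART_B1 stayed outside the lists. Other entries, such as BEL, Copia1, DOC6, R1, PROTOP_A and PROTOP_B, were in no list, so list counts do not cover whole classes. A name shared by 2 entries was left out, so the separate entries Gypsy2 and GYPSY2 are missing from the other gypsy-superfamily counts. The plan was to name, for each comparison, the called elements with the 10 largest rises and 10 largest falls, and the fixed elements. The text gives only a part of these. Other elements named, such as BATUMI, PROTOP_B, FW, BS2 and IVK, were chosen after their values were seen. A list's median log2 ratio was ranked among 10000 random lists of equal size matched in 4 bins of mean level. Set tests with camera were not run.

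Relations across elements used log2 ratios with a pseudocount of 1, Pearson and Spearman correlations, 100000 permutations and Benjamini-Hochberg adjustment over 21 pairs. The Nxf2-KD and Panx-KD changes were set against 1000 simulated unchanged pairs that share the EGFP-KD reads. Peaks were shared at an overlap of 1 bp, against 1000 random placements within chromosomes, or 200 for the Jaccard index. Alternatives were pseudocounts of 0.1 and 10, no filter, a mean of at least 10, median centring and other peak overlaps. Added after the data were seen were a pseudocount of 1, totals without element reads, EGFP-KD reads divided at random, other settings of the correlation and peaks without heterochromatin sequences. Genes at peaks were not analysed here. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1.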

Results

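The series held 31 samples from ovarian somatic cells (OSC), a cultured *Drosophila melanogaster* line derived from the follicle cells of the ovary. In these cells Piwi, guided by its bound small RNAs (piRNAs), silences transposable elements. Panx is a nuclear protein needed for that silencing, and Nxf2 is a variant of the nuclear RNA export factors. RNA sequencing covered 7 samples with knockdown (KD) of EGFP as the control (2), Nxf2 (2), Panx (2) or Piwi (1). Crosslinking and immunoprecipitation (CLIP) of myc-tagged Nxf2 covered 6 samples with and without ultraviolet (UV) crosslinking and 8 samples of EGFP-KD or Piwi-KD cells. CLIP of Piwi itself covered 3 samples, and small RNAs bound to Piwi covered 1. Chromatin immunoprecipitation of H3K9me3, a repressive histone mark, covered 4 samples with 2 inputs. Each CLIP experiment had size-matched input RNA (SMInput) as its background. The deposited tables gave 1 value per condition for each transposable element consensus entry, so no difference between conditions has a replicate check. Intervals below are 95% counting intervals that compare these libraries only. Reads are not independent molecules, and the intervals and the floor of 3 counts cover counting error alone. The genes for Nxf2, Panx and Piwi were not in the tables, so the knockdowns themselves were not analysed here. Marker genes of germ cells or follicle cells were also absent and not analysed here.

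Library totals ran from 8968998 reads (Piwi-KD) to 9852335 reads (EGFP-KD) in RNA sequencing. They ran from 426679 reads (no-UV IP) to 2746550 reads (UV SMInput) in the CLIP experiments, and the small RNA library had 3187937 reads. Elements took 5.68% of RNA reads in EGFP-KD cells (Wilson interval 5.66 to 5.69%), 9.64% in Nxf2-KD cells, 10.3% in Panx-KD cells and 16.4% in Piwi-KD cells. COPIA alone supplied 65.8% of the element reads in EGFP-KD cells and 59.4% in Nxf2-KD cells. Elements took 37.7% of the Piwi-bound small RNA reads, and DM412 was the largest source with 8.23% of them.

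Loss of Nxf2 raised the RNA of retrotransposons that are expressed in follicle cells. MDG1 rose 60.7-fold (interval 57.0 to 64.6), from 14.7 to 891 RPKM. GYPSY rose 29.4-fold (27.9 to 30.9), DM297 rose 26.8-fold (24.5 to 29.5), DM412 rose 26.2-fold (23.8 to 28.9) and TABOR rose 13.5-fold (12.8 to 14.1). GYPSY5, which had only 9 reads in EGFP-KD cells, rose 14.7-fold (7.49 to 32.9). Of 65 elements tested, 22 rose at least 2-fold with an interval above 1 and 0 fell. STALKER4 rose 7.32-fold, QUASIMODO 4.63-fold, Gypsy2 4.26-fold and DM412B, with 3 control reads, 12.6-fold. Transib1, a DNA transposon with 0 reads in EGFP-KD cells, was 13.7-fold higher at the floor of 3 counts. The I element rose 2.78-fold, GTWIN 2.75-fold and ROO 2.47-fold. Several named elements stayed under the 2-fold threshold: DM176 had a ratio of 1.95, DOC 1.93, BLOOD 1.66, COPIA 1.53, ZAM 1.39 and IDEFIX 1.26.

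Among the lists fixed in advance, 10 of 14 tested somatic LTR retrotransposons rose in Nxf2-KD cells, with a median ratio of 5.82, at percentile 99.94 of random lists of like abundance. Of the other gypsy-superfamily elements, 1 of 11 rose (MDG3, 3.16-fold), and the list median was 1.02. Left out of this count were 2 separate entries that share a list name, Gypsy2 (ratio 4.26) and GYPSY2 (0.993). Of copia and Bel/Pao elements 2 of 7 rose (ROO and BATUMI), of other non-LTR elements 3 of 10 rose (I, IVK and BS2), and of DNA transposons 1 of 4 rose. Copia1 (ratio 2.03), DOC6 (2.75) and PROTOP_B (2.09) rose as well but were in no list. BEL, R1 and PROTOP_A were in no list either. List counts here and below therefore cover the listed entries only, not whole classes of elements. Of the germline-dominant elements, a list that overlaps the others and marks germ cells, 3 of 8 rose: I, ROO and MDG3. Of the telomeric list, HETA and TAHRE were matched and had too few reads to be tested. The entries TART and TART_B1 were not matched to the list by name, and their ratios in Nxf2-KD cells were 0.830 and 0.850, with intervals below 1 short of the threshold. The median log2 ratio of the tested elements was 0.48, and with the log2 ratios centred on this median 13 elements rose and 4 fell. With a pseudocount of 10 RPKM, 10 elements rose.

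Loss of Panx raised nearly the same set by nearly the same amounts. MDG1 rose 58.0-fold (54.5 to 61.7), DM297 36.8-fold (33.6 to 40.3), DM412 35.5-fold (32.2 to 39.1), GYPSY 28.9-fold (27.5 to 30.5) and TABOR 14.4-fold (13.8 to 15.1). GYPSY5 rose by 4.17 on the log2 scale, STALKER4 rose 7.77-fold and QUASIMODO 6.33-fold, while IDEFIX had a ratio of 1.34 and ZAM 1.53. Again 22 of 65 elements rose and 0 fell, and 20 of the 22 were those that rose in Nxf2-KD cells, with the EGFP-KD reads shared by both comparisons. BATUMI and PROTOP_B passed the threshold in Nxf2-KD cells and not in Panx-KD cells, and DM176 and FW passed it in Panx-KD cells and not in Nxf2-KD cells. Of the somatic LTR list 11 of 14 rose (median ratio 7.01, percentile 99.97), of the other gypsy-superfamily list 1 of 11, of the copia and Bel/Pao list 1 of 7, of the other non-LTR list 4 of 10, of the DNA transposons 1 of 4 and of the germline-dominant list 3 of 8. After median centring 14 elements rose and 3 fell, and with a pseudocount of 10 RPKM 10 rose.

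Compared directly, Nxf2-KD and Panx-KD cells differed in no element by 2-fold or more: 0 of 65 elements were higher and 0 lower. DM297 had a ratio of 0.730 (0.713 to 0.747), QUASIMODO 0.731 (0.678 to 0.789) and DM412 0.740 (0.722 to 0.759), with intervals below 1 but short of the 2-fold threshold. MDG1 had a ratio of 1.05 (1.03 to 1.06) and GYPSY 1.01. Across the 65 elements, which are not independent replicates, the log2 changes in both knockdowns had r = 0.994 and rho = 0.965, with a covariance of 1.85. Unchanged libraries simulated with the same shared EGFP-KD reads gave r = 0.484 but a covariance of 0.00946. Dividing the EGFP-KD reads at random between the ratios gave r = 0.983.

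**Figure D1:**
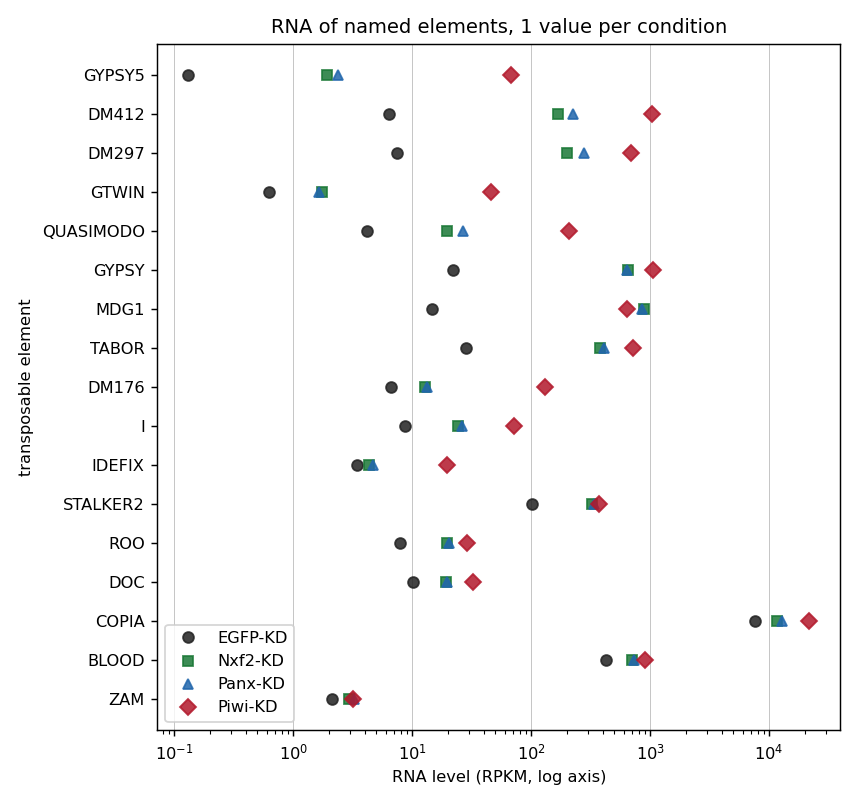
RNA level in RPKM (log axis) of the named elements that could be tested, with 1 point per condition and no error bars because each condition has 1 value. In GTWIN the Nxf2-KD to EGFP-KD ratio was 2.75 and the Piwi-KD to EGFP-KD ratio was 72.6, while in MDG1 these ratios were 60.7 and 43.8.

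Loss of Piwi raised more elements, and some of them far more than loss of Nxf2 did. GYPSY5 rose 514-fold (271 to 1126), from 9 to 4214 reads, DM412 rose 162-fold (148 to 179), DM297 92.9-fold (84.9 to 102), GTWIN 72.6-fold (53.8 to 101) and QUASIMODO 49.6-fold (44.0 to 56.0). GYPSY rose 48.2-fold, MDG1 43.8-fold, STALKER4 28.2-fold, TABOR 25.4-fold, DM176 19.8-fold and the I element 8.28-fold. Of 65 elements 28 rose and 2 fell: DIVER to a ratio of 0.451 (0.423 to 0.481), a call that ended at a log2 ratio of -0.97 with totals without element reads, and GYPSY6A, with 6 against 20 reads, to 0.330 (0.108 to 0.851). IDEFIX (5.61-fold), DOC (3.20-fold), COPIA (2.84-fold) and BLOOD (2.11-fold) rose in Piwi-KD cells. ZAM had an interval of 1.23 to 1.85 and stayed under the threshold. Of the somatic LTR list 13 of 14 rose, with a median ratio of 35.2 (percentile 99.99). Of the other gypsy-superfamily list 1 of 11 rose, of the copia and Bel/Pao list 2 of 7 rose and 1 fell, of the other non-LTR list 5 of 10 rose, of the DNA transposons 1 of 4 rose, and of the germline-dominant list 4 of 8 rose and 1 fell. All 20 elements that rose in both Nxf2-KD and Panx-KD cells also rose in Piwi-KD cells, and no element passed the threshold in opposite directions in any pair of knockdowns. After median centring 23 elements rose and 7 fell.

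The direct comparison of Piwi-KD with Nxf2-KD cells was added after the tables were seen. In it 14 of 65 elements were higher in Piwi-KD cells and 0 were lower. GYPSY5 was higher by 5.13 on the log2 scale (interval 29.3-fold to 42.3-fold), GTWIN was 26.4-fold higher (21.8 to 32.3), QUASIMODO 10.7-fold (10.1 to 11.4), DM176 10.2-fold (9.48 to 10.9), DM412 6.18-fold (6.06 to 6.31) and IDEFIX 4.45-fold (3.90 to 5.10). GYPSY (ratio 1.64), STALKER2 (1.13), ROO (1.48) and BLOOD (1.27) stayed under 2-fold, and MDG1 had a ratio of 0.722 (0.713 to 0.732). Of the somatic LTR list 8 of 14 were higher in Piwi-KD cells. The Piwi-KD condition had a single sample, and the degree of depletion in each knockdown was not analysed here.

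**Figure D2:**
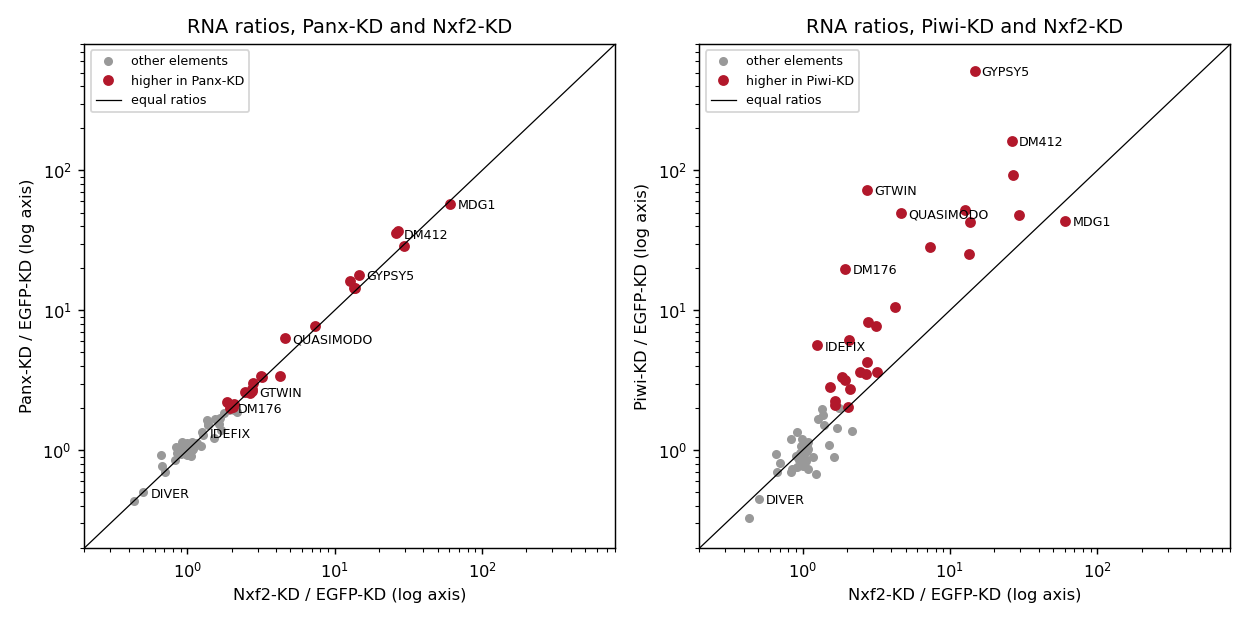
RNA ratio to EGFP-KD of each of 65 tested elements (log axes), Nxf2-KD on the horizontal axes and Panx-KD (left) or Piwi-KD (right) on the vertical axes, with red points for the elements that rose in the knockdown on the vertical axis. Panx-KD points lie near the line of equal ratios (r = 0.994 on the log2 scale), while GYPSY5, GTWIN, QUASIMODO and DM176 lie above it in Piwi-KD cells, by 10.2-fold or more.

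CLIP of myc-Nxf2 asked which RNAs are bound by the protein, with uncrosslinked cells and SMInput as backgrounds. Against UV SMInput, the UV IP was enriched for STALKER4 (11.4-fold, 5.26 to 28.1), DM297 (9.91-fold, 7.43 to 13.4), GYPSY (9.80-fold, 8.10 to 11.9), DM176 (7.30-fold, 4.57 to 12.1) and QUASIMODO (7.27-fold, 4.23 to 13.1). FW, a non-LTR element with 2 input reads, was 16.6-fold enriched (3.87 to 150). IDEFIX, at 0 reads in the input, was 7.39-fold enriched at the floor of 3 counts, with an interval starting at 4.97. Of 63 elements 22 were enriched and 2 depleted, the ribosomal DNA elements R2 (0.462, 0.208 to 0.925) and R1 (0.358, 0.109 to 0.928). Enrichment covered 12 of 14 somatic LTR elements (median ratio 6.17, percentile 99.95), against 1 of 13 other gypsy-superfamily, 1 of 6 copia and Bel/Pao, 3 of 10 other non-LTR (with 1 depleted), 0 of 2 DNA transposon and 4 of 10 germline-dominant elements. COPIA, the most abundant element, had a ratio of 0.897 (0.876 to 0.919) and ZAM 0.951. After median centring 14 elements were enriched and 7 depleted, and with a mean of at least 10 RPM 12 of 21 elements were enriched and 0 depleted.

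The UV IP exceeded the no-UV IP in 21 of 63 elements and fell below it in 0. QUASIMODO was 20.3-fold higher (3.51 to 816), with 1 read in the no-UV IP, GYPSY 13.3-fold, DOC6 11.4-fold (3.78 to 56.1), DM297 8.11-fold (4.46 to 16.5), BLOOD 7.51-fold (5.93 to 9.65) and COPIA 3.24-fold (3.04 to 3.47). By list, 10 of 14 somatic LTR, 5 of 11 other gypsy-superfamily, 1 of 5 copia and Bel/Pao, 1 of 10 other non-LTR, 0 of 3 DNA transposon and 2 of 10 germline-dominant elements were higher. The input rose with crosslinking as well: elements took 1.07% of UV SMInput reads and 0.102% of no-UV SMInput reads. Between these inputs COPIA differed 15.5-fold (14.5 to 16.6), BLOOD 12.4-fold and GYPSY 5.68-fold, and 26 elements were higher in UV SMInput and 1, DM1731, lower. With both inputs taken into account, a comparison added after the tables were seen, the UV effect had a median ratio of 0.606 over 31 elements, with 11 above 1 and 20 below. It passed the threshold upward in DM297 (3.00, 1.17 to 7.75) and GYPSY (2.34, 1.02 to 5.34). It passed it downward in COPIA (0.209, 0.190 to 0.230), STALKER2 (0.169), INVADER1 (0.165) and DIVER (0.398). BLOOD (0.606, 0.428 to 0.859) and Gypsy1 (0.589, 0.505 to 0.689) had intervals below 1 short of the threshold. For 32 of 63 elements a library held 0 reads and no such value could be formed. Some of the values formed, such as those of HMSBEAGLE and ROVER, rest on 1 read in each no-UV library.

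In EGFP-KD cells of the myc-Nxf2 line, which were also depleted of endogenous Nxf2 per the labels, Nxf2 recovered many retrotransposon RNAs above SMInput. QUASIMODO was enriched 30.7-fold (18.5 to 54.6), DOC 25.5-fold (11.1 to 72.0), MDG3 22.5-fold (12.1 to 46.4), GYPSY 19.0-fold (16.6 to 21.7), DM297 14.1-fold (11.7 to 17.2), DM412 13.0-fold (8.12 to 21.7) and MDG1 10.8-fold (7.66 to 15.5). GTWIN, with 42 IP reads and 0 input reads, was 31.5-fold enriched at the floor of 3 counts, with an interval starting at 24.5. IDEFIX and Gypsy2, each with 1 input read, had ratios of 87.8 (14.9 to 3557) and 51.8 (8.41 to 2134). Of 78 elements 39 were enriched and 3 depleted (R2, DNAREP1 and M4DM). The I element (7.44-fold), ZAM (7.43-fold), ROO (5.23-fold), BLOOD (4.16-fold) and COPIA (2.27-fold) were enriched too. The somatic LTR list had 14 of 16 enriched members (median ratio 10.4, percentile 99.82), other gypsy-superfamily 9 of 13, copia and Bel/Pao 5 of 8, other non-LTR 5 of 14 with 1 depleted, DNA transposons 0 of 4, germline-dominant 8 of 12 and telomeric 0 of 1. Of the 22 elements enriched in the UV experiment, 21 were enriched here. Median centring left 23 elements enriched and 13 depleted, and turned the log2 ratio of COPIA to -0.31.

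Piwi depletion lowered the recovery of many of these RNAs with Nxf2 relative to their input. The ratio of IP over SMInput in Piwi-KD cells to that in EGFP-KD cells was 0.0600 in QUASIMODO (0.0320 to 0.107), 0.0604 in DOC (0.0168 to 0.204), 0.113 in the I element (0.0801 to 0.160), 0.126 in GYPSY (0.109 to 0.146), 0.130 in DM176 (0.0862 to 0.195) and 0.146 in DM297 (0.118 to 0.179). ZAM had a ratio of 0.0835 (0.0168 to 0.363), HMSBEAGLE 0.153, DM412 0.172, MDG1 0.231, TABOR 0.381 and ROO 0.452. Of 78 elements 23 fell and 2 rose: BEL (2.22, 1.51 to 3.27) and M4DM (6.39, 1.03 to 67.2, with 2 reads in the control IP). COPIA (0.836, 0.805 to 0.869) and BLOOD (0.687, 0.635 to 0.743) were lower with intervals below 1, short of the 2-fold threshold. Falls covered 11 of 15 somatic LTR (median ratio 0.192), 6 of 11 germline-dominant (median 0.158), 3 of 13 other gypsy-superfamily, 2 of 8 copia and Bel/Pao, 4 of 14 other non-LTR and 0 of 4 DNA transposon elements. Median centring, which shifted all elements by the median log2 ratio of -0.93, left 17 falls and 9 rises.

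Both sides of that ratio moved. In the Piwi-KD SMInput 18 of 78 elements rose and 0 fell, led by MDG1 (81.6-fold), DM412 (33.2-fold), DM297 (13.1-fold), GYPSY (10.3-fold) and QUASIMODO (9.33-fold). In the Piwi-KD IP against the EGFP-KD IP 7 elements rose and 14 fell. MDG1 rose 18.9-fold (16.3 to 21.9), DM412 5.71-fold and TABOR 3.22-fold. ZAM fell to 0.118 (0.0304 to 0.332), GYPSY4 to 0.176, DOC to 0.186, HMSBEAGLE to 0.203, IDEFIX to 0.250 and the I element to 0.311. By list, 4 of 16 somatic LTR elements rose and 4 fell, and 4 of 13 germline-dominant elements fell. Against its own input, the Piwi-KD IP was enriched for 26 elements and depleted of 3, and 21 of the 26 were among the 39 enriched in EGFP-KD cells.

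**Figure D3:**
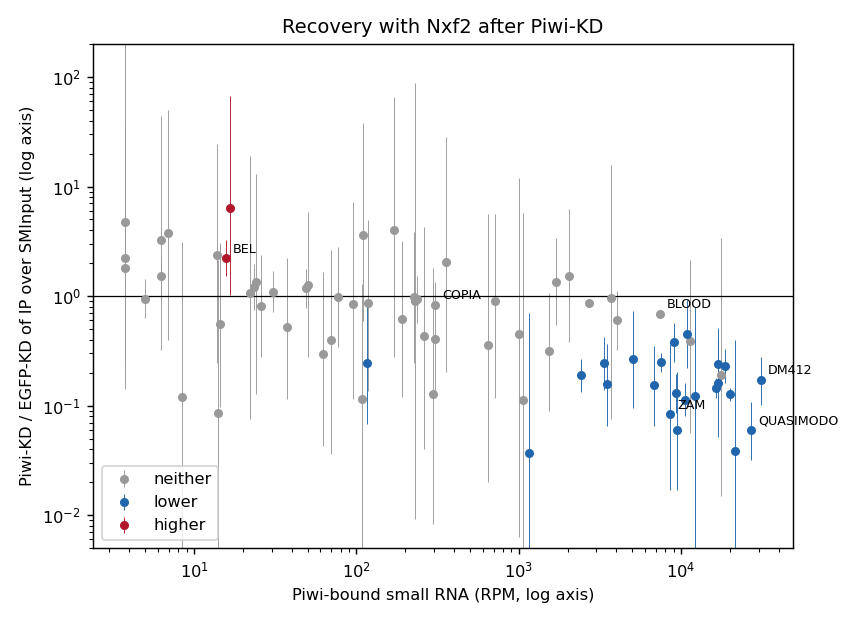
Ratio of IP over SMInput in Piwi-KD cells to that in EGFP-KD cells (log axis) against the Piwi-bound small RNA level in RPM (log axis), 1 point per element with a 95% counting interval, cropped at the frame. Falls were called in 20 of the 25 elements with the most small RNA and in 3 of the next 25, among them DMCR1A at 115 RPM, less than COPIA at 303 RPM.

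CLIP of Piwi itself asked which element RNAs this protein binds. Against SMInput the Piwi IP was enriched for MDG1 (82.8-fold), QUASIMODO (49.4-fold, 19.1 to 183), the I element (37.6-fold, 27.8 to 52.1), DM297 (33.4-fold, 25.6 to 44.5), STALKER4 (32.8-fold, 17.1 to 72.2) and DOC (27.0-fold, 12.2 to 74.2). GYPSY (19.3-fold), DM412 (17.9-fold), ROO (16.0-fold), COPIA (7.36-fold) and BLOOD (3.98-fold) were enriched as well. GTWIN was 2.64-fold and GYPSY5 2.23-fold higher at the floor of 3 counts, both with 0 input reads. Of 98 elements 56 were enriched and 3 depleted, R1 (0.304), DMRT1B (0.243) and R2 (0.203). All 17 testable somatic LTR elements were enriched (median ratio 14.4, percentile 98.51), with 9 of 16 other gypsy-superfamily, 5 of 9 copia and Bel/Pao, 10 of 18 other non-LTR with 2 depleted, 3 of 5 DNA transposon, 8 of 13 germline-dominant with 1 depleted and 0 of 2 telomeric elements. All 22 elements enriched in the UV Nxf2 IP were among the 56. Elements took 15.1% of the Piwi IP reads and 2.80% of its SMInput reads, and after median centring 24 elements were enriched and 8 depleted.

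Elements with more Piwi-bound small RNA responded more often. The 20 elements with the most small RNA held 82.9% of the element small RNA reads, led by DM412 (31006 RPM), GTWIN (29585 RPM) and QUASIMODO (27121 RPM). Of these, 18 could be tested for RNA, and 13 rose in Nxf2-KD cells, 14 in Panx-KD cells and 16 in Piwi-KD cells. Splitting the tested elements by small RNA level into 3 groups, 3 of 22, 5 of 21 and 14 of 22 rose in Nxf2-KD cells from the lowest to the highest group. In Piwi-KD cells 3 of 22, 6 of 21 and 19 of 22 rose. Recovery with Nxf2 fell on Piwi depletion in 0 of 25, 3 of 25 and 20 of 25 elements, with median ratios of 1.21, 0.836 and 0.172. Input contributed to this: in the highest group SMInput rose in 16 of 26 elements, while the IP fell in 11 and rose in 5, with a median IP to IP ratio of 0.511. Starting enrichment differed too: EGFP-KD IP over SMInput had median ratios of 1.24, 2.46 and 10.3 from the lowest to the highest group. Of the 23 falls 22 were among the 39 elements enriched there, and this enrichment is the denominator of the effect. Small RNA level and starting enrichment therefore cannot be told apart here. COPIA had 303 RPM of small RNA and BEL 15.7 RPM.

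Across elements, the small RNA level and the Piwi-KD effect on Nxf2 recovery had r = -0.732 and rho = -0.735 over 77 elements (permutation test, 2-sided, p = 1e-05, the smallest that 100000 permutations give, adjusted p = 1.9e-05 for rho). Without the 2 elements farthest from the median small RNA level, r was -0.707. The small RNA level and the UV IP over SMInput had r = 0.673 and rho = 0.682 over 62 elements (adjusted p = 1.9e-05 for rho, r = 0.651 without 2 elements). The small RNA level and the RNA change in Nxf2-KD cells had r = 0.523 and rho = 0.526 over 63 elements (p = 2e-05 and adjusted p = 2.8e-05 for rho, r = 0.496 without 2 elements). The RNA change in Nxf2-KD cells and the UV IP over SMInput had r = 0.576 and rho = 0.633 over 52 elements (adjusted p = 1.9e-05 for rho, r = 0.570 without 2 elements). These are 4 of 21 relations computed, and the largest adjusted p among the 21 was 0.034. Elements are not independent replicates, and some pairs of measures share a library. The Piwi-KD effect has the EGFP-KD IP over SMInput as its denominator, and that ratio was itself higher where small RNA was abundant.

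H3K9me3 peaks in Nxf2-KD and Panx-KD cells lay largely at the same places. Of 3497 peaks in Nxf2-KD cells 89.0% overlapped a Panx-KD peak by at least 1 bp, and of 4023 Panx-KD peaks 76.7% overlapped a Nxf2-KD peak. Random placements within chromosomes gave medians of 32.8% and 29.8% over 1000 placements. The peaks covered 9.25 Mb and 10.2 Mb, and the Jaccard index of base pairs was 0.713, against at most 0.141 in 200 random placements. Random placements spread the peaks evenly over each chromosome. Without a list from control cells, an overlap above them does not show that either knockdown shaped it. On the dm3 heterochromatin sequences 91.5% of Nxf2-KD and 84.0% of Panx-KD peaks were shared, against 87.4% and 72.4% on the chromosome arms, and X had the lowest share of Panx-KD peaks (63.0%). Peaks covered 4550 kb (Nxf2-KD) and 4836 kb (Panx-KD) of 9226550 bp of heterochromatin sequences. On the arms they covered 4700 and 5332 kb of 119402657 bp. Random overlap is thus more frequent on the heterochromatin sequences. Random shares were not computed for the 2 parts, so these percentages do not show better agreement there. The highest-scoring Nxf2-KD peak was at 3R 6783436 to 6789245 (score 3210), followed by 2L 22756710 to 22766981 (3177) and 2L 10138164 to 10143533 (3142), all overlapping Panx-KD peaks. The highest-scoring Panx-KD peak was at X 1732965 to 1743546 (3195), followed by 3L 24411476 to 24418478 (3167) and 2RHet 168159 to 179296 (3136), all overlapping Nxf2-KD peaks. A score of exactly 3100 was tied among 5 Nxf2-KD and 16 Panx-KD peaks, so scores do not order the peaks at that value. The highest-scoring peaks without an overlap were at 2RHet 2236625 to 2249916 in Nxf2-KD cells (3100, 2491 bp from the nearest Panx-KD peak) and at 2R 362333 to 375514 in Panx-KD cells (3010, 119 bp from the nearest Nxf2-KD peak). No peak list of EGFP-KD cells was used here, so gain or loss of the mark was not analysed here, and the genes at these peaks were not analysed here.

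**Figure D4:**
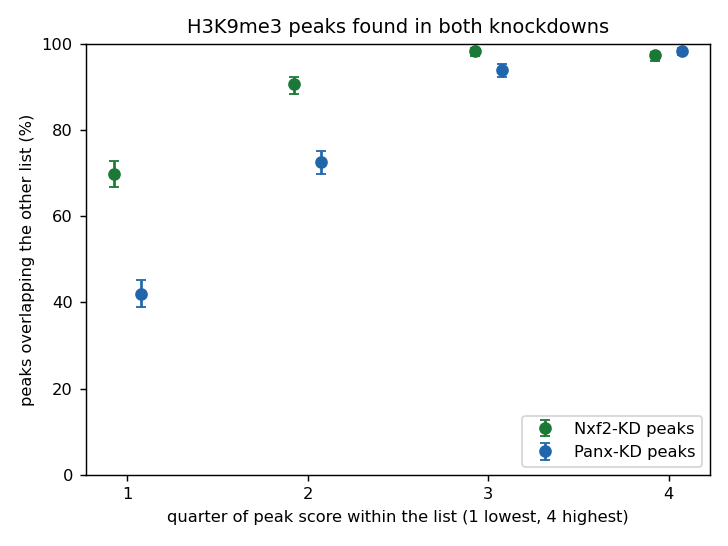
Percent of H3K9me3 peaks that overlap the other knockdown's list, in 4 groups of rising peak score within each list, with 95% Wilson intervals as bars. Sharing ran from 69.8% in the lowest group to 97.4% in the highest for Nxf2-KD peaks and from 42.0% to 98.4% for Panx-KD peaks. Shared peaks were also longer, with a median of 1855 against 1032.5 bp in Nxf2-KD and 1880 against 920 bp in Panx-KD cells. Longer peaks overlap more often at random, and random shares were not computed per group.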

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

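The alternatives chosen only after the results were seen were a pseudocount of 1, totals without element reads, EGFP-KD reads divided at random, the correlation with a pseudocount of 0.1 or a mean of at least 10, and peaks without heterochromatin sequences. Of these, only totals without element reads and peaks without heterochromatin sequences moved a count or share: 1 element fell in Piwi-KD RNA (2 in the report), since DIVER moved from a log2 ratio of -1.15 to -0.97 and lost its call, and 87.4% of Nxf2-KD and 72.4% of Panx-KD peaks were shared. A pseudocount of 0.1 left every count of called elements within 1.5 times the reported one.

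A pseudocount of 10 left 10 elements higher in Nxf2-KD RNA, 10 in Panx-KD RNA and 0 lower in Piwi-KD RNA. It left 14 enriched and 0 depleted in UV IP over SMInput, 0 depleted in the EGFP-KD CLIP and 1 higher in the Piwi-KD effect, where Gypsy2 reversed to a log2 ratio of 0.63. By construction this setting shrinks ratios of low values. Without a filter 1 element was lower in Nxf2-KD RNA and 1 in Nxf2-KD against Panx-KD RNA. A mean of at least 10, which tests fewer elements, left 1 lower in Piwi-KD RNA, 12 enriched and 0 depleted in UV IP over SMInput, 1 depleted in the EGFP-KD CLIP and 1 higher in the Piwi-KD effect.

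Median centring subtracts the median log2 ratio, so it adds falls wherever most elements rose. It gave 13 higher and 4 lower in Nxf2-KD RNA, 14 and 3 in Panx-KD RNA, and 7 lower in Piwi-KD RNA. It gave 14 enriched and 7 depleted in UV IP over SMInput, 23 and 13 in the EGFP-KD CLIP, 24 and 8 in the Piwi CLIP, and 9 higher in the Piwi-KD effect. COPIA reversed to -0.31 in the EGFP-KD CLIP. In the Piwi CLIP the floor ratios of GTWIN and GYPSY5, with 0 input reads, moved to -0.21 and -0.45, which does not show a reversal. Whether the shared shift is technical was not tested.

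Reciprocal overlap of 0.5 of each peak gave 71.5% of Nxf2-KD and 62.2% of Panx-KD peaks shared, and the upper part of each list by score gave 78.0% for Panx-KD. The cause was not tested. The correlation of Nxf2-KD and Panx-KD changes ran from 0.991 to 0.996 over its pseudocounts and filters, and from 0.972 to 0.994 over the same settings with the EGFP-KD reads divided at random.

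No paired analysis was possible because each table has 1 column per condition. For that reason limma, limma-trend, edgeR, DESeq2, a replicate block, leaving out each replicate, the correlation with controls separated by replicate and camera were not run. Depth limits what the CLIP comparisons can show. Simulated 2.5-fold rises were recovered in 64% of elements for the EGFP-KD CLIP, 59% for the Piwi CLIP and 45.5% for the Piwi-KD effect. For Nxf2-KD RNA 98% were recovered. Recovery of falls was not simulated.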

Other observations

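All tests in this part were chosen only after the results were seen.

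Without crosslinking the myc-Nxf2 IP still exceeded its SMInput in 10 of 63 elements and fell below it in 0, while 29 elements gave no ratio. Among the 10 were STALKER2 (18.2-fold, 5.09 to 98.9, with 3 input reads), COPIA (4.29-fold, 3.92 to 4.70), GYPSY (4.19-fold, 1.88 to 9.36) and BLOOD (3.91-fold, 2.78 to 5.49). With UV these ratios were 3.09, 0.897, 9.80 and 2.37. Enrichment over SMInput alone therefore does not show that recovery depended on crosslinking. The median was 3.796 over 34 elements without UV and 1.89 over 62 with UV, which are different sets. Without UV, 1 read on each side already gave a ratio of 3.91, as in HMSBEAGLE and ROVER. Copia1 and MDG3, with 0 IP reads, entered at floor ratios of 2.34 and 1.95. The no-UV median therefore reflects depth and single reads and does not measure typical enrichment. COPIA and Copia1 both had 966 small RNA reads, the only equal pair among 76 elements with at least 100 reads in that library.

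Of the 23 elements whose recovery with Nxf2 over SMInput fell on Piwi depletion, 9 had no called rise of SMInput and had a median IP to IP ratio of 0.250 (quartiles 0.176 to 0.313), but their selection largely fixes a low ratio, so this value decides nothing. In the 14 with a risen SMInput, among them MDG1 and DM412, that median was 0.672 (0.439 to 2.89), and a rising input cannot be told apart from lower recovery. A less efficient Piwi-KD IP also stays open: 15 enriched elements outside the group with the most small RNA had a median effect of 0.836 (0.159 to 1.14), against 0.161 in the 23 inside it, and the ranges overlap. A narrower look, added once that gave no answer, at elements with at least 50 control input reads gave 1.14 in 8 and 0.138 in 6, but the 8 started from a lower enrichment (2.48 against 8.75). That Piwi may guide Nxf2 to these RNAs was not tested apart from these.

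Rises were larger in Piwi-KD than in Nxf2-KD cells for GYPSY5, GTWIN and QUASIMODO but not for MDG1. If Piwi depletion were only stronger, log2 rises could be a constant multiple of the others. Over 20 elements that rose in all 3 knockdowns the best multiple was 1.44, and the median departure from it was 0.61, above the largest Nxf2-KD to Panx-KD difference of 0.45. GTWIN departed most, by 4.13. This argues against 1 common scale, but a single Piwi-KD library and element-specific responses to depth of depletion stay open, and a role of Piwi without Nxf2 was not tested.

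Among the elements tested for RNA, GYPSY4, HMSBEAGLE and ZAM had abundant Piwi-bound small RNA without a called rise of their RNA. In these elements too few RNA reads are not the limit, since the highest upper bound over the 3 knockdowns was 1.88. Elements under the RNA level filter were left out before this test. ROVER (17684.5 RPM) and GYPSY10 (8777 RPM) were among those left out, so few reads can be the limit for other elements rich in small RNA. Missing recovery with Nxf2 stays open: 100% of the 3 were enriched in the EGFP-KD CLIP, but 0% in the UV IP over SMInput, where the ratios were 2.85 for GYPSY4 (0.945 to 9.01), 1.90 for HMSBEAGLE (0.803 to 4.43) and 0.951 for ZAM (0.159 to 4.16). Copies without activity in these cells may be a candidate explanation, which was not tested.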
